A study of Arabidopsis thaliana with 8 samples.

How the data were processed

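RNA from whole plants at developmental stage 3.90 was labelled with biotin and hybridised to 1-colour Affymetrix ATH1 arrays. Per the labels, the plants grew in sand in a growth room at 23 degrees Celsius, humidity 34 and light 160, with 0.5 times Long Ashton nutrients and 1 mM calcium chloride, after 48 hours of stratification at 4 degrees Celsius. Samples were grouped by accession as the labels give it, with 4 arrays of Cal-0 and 4 of Col-4. The labels number the replicates from 1 to 4 but do not say that they come from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical.

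The deposited values are probe set intensity on a linear scale, made by the authors with MAS5 per the submitters' processing notes; its version and settings are not given in the sources used here. The mean of each array after trimming 2% at either end was 100.01, so the values had been scaled to a common level. No detection calls were used here, and low signals have no background estimate beside them. Signals near 0 therefore carry little information, and differences on the log2(signal + 16) scale understate the change of low genes.

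Genes were named from the table that pairs the probe sets with the platform annotation, with symbols updated through gene identifiers to the RefSeq annotation of TAIR10.1. Of the probe sets that are not controls, 13513 had a single gene, 503 had several and 8730 were not in the table and stay unnamed here. Of the tested probe sets 54.7% had a single gene. No gene was named from a probe set with several. From that annotation only names and the order of neighbouring genes were used, and no coordinates are given.

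Signals were transformed as log2(signal + 16) without further normalization. Probe sets with a mean signal of at least 25 over the 8 arrays were tested, 15165 in all, and 7581 were left out by that filter. Cal-0 was compared with Col-4 in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, two-sided, no covariate), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The residual degrees of freedom were 6. Gene lists were tested with camera at a preset correlation of 0.01, with 1 probe set per gene, that of the highest mean signal, and at least 3 tested members.

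The tests, the alternatives, 24 gene lists and the rule for named genes were fixed before the data were examined. The rule took the 12 largest called differences in each direction among probe sets with a single gene, no overlap between the accessions and a mean signal of at least 100 in the higher one. It added up to 4 called members of each list or, where none was called, the member with the smallest p, and 7 genes of calcium transport and flowering whatever their values. The latter were not analysed here because the gene table named no probe set for them. The table named probe sets for 43 of the 366 list entries, 38 of them tested, and 6 of the 24 lists had at least 3 tested members. After the table had been read, and before any test, 20 lists of gene families were added, and up to 4 called members of each were named by the same rule; 19 of them had enough tested members.

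Whether replicate numbers pair the samples was checked from the deviations of each array from its accession mean. Arrays with the same number correlated at 0.278, 0.376, 0.478 and 0.403. Between replicates 3 and 4 of different accessions, unlike numbers correlated at only 0.142 and 0.035. There the numbers appeared to pair the samples, on the evidence of the data and not of the labels. Between replicates 1 and 2 unlike numbers correlated at 0.273 and 0.382, as well as like ones. There pairing by number was not seen, and the shared variation may belong to the set of arrays. The replicate number and the division between arrays 1 to 4 and arrays 5 to 8 were each used as a block in an alternative. No 2 arrays held the same values. The correlation between arrays of an accession lay between 0.947 and 0.975, and that between accessions overlapped it, at 0.94 to 0.962.

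The alternatives were pseudocounts of 1 and 50, no filter or a mean signal of at least 100, quantile normalization, median centring, an intensity trend with robust estimation, array weights, the replicate block, the block of arrays, probe sets without cross-hybridisation suffix, and each array left out in turn. A fit with the 3′ to 5′ ratio of each array as a covariate, the mean log2 ratio of the GAPDH and actin control probe sets, was added after seeing the data. For the lists they included an estimated correlation, fry and the mean of all probe sets of a gene. Of these, fry answers another question, testing a list against no change, where camera tests it against the other genes.

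The limma step was tested on simulated data with the real means and residual spreads, 200 probe sets changed in each of 5 runs of 14888 tested on average. It recovered 11.9% of the changes of 0.5 on the log2 scale, 70.1% of those of 1 and 98.2% of those of 2, none with the wrong sign. A mean of 5 unchanged probe sets per run were called. In 20 simulated runs on 15165 probe sets, the list test called the shifted list of 30 genes in all 20 and none of the 100 unchanged lists. The simulated genes varied independently, and the fixed lists that were tested had only 3 or 4 tested members. These runs therefore do not show how the test behaves for small lists or for genes that vary together.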

Results

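Transcript levels were measured in whole Arabidopsis plants of 2 accessions grown under the same conditions in sand, on a dilute nutrient solution with 1 mM calcium chloride. Cal-0 is labelled a calcicole, a plant of lime-rich soils, and Col-4 a non-calcicole. Each accession was represented by 4 arrays, 8 in all, hybridised to the ATH1 array, which carries probe sets for most Arabidopsis genes known when it was designed. The deposited MAS5 signals covered 22810 probe sets, of which 64 were controls. Array medians over the other probe sets lay between 44.0 and 50.1 signal units, and the number of arrays, not a read depth, limits the precision here. All plants received the same calcium dose, so the comparison addresses how the accessions differ under that supply and not how either responds to lime.

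ECS1 (AT1G31580), which encodes a cell wall protein, had a signal of 859 ± 139 in Cal-0 and 6788 ± 1695 in Col-4 (SD, n = 4 arrays each), a log2 difference of -2.94 on the scale of log2(signal + 16). The thionin gene AT1G66100, coding for a small antimicrobial peptide, was at 7.38 ± 4.97 in Cal-0 against 232 ± 158 in Col-4. In the other direction, AT4G33720, which encodes a protein of the pathogenesis-related 1 family, reached 919 ± 256 in Cal-0 and 194 ± 88.8 in Col-4. MPC (AT3G19350), a maternally expressed gene related to the C-terminal part of poly(A)-binding proteins, was higher in Cal-0 by 3.09 on the log2 scale. limma called 651 of 15165 probe sets at a Benjamini-Hochberg adjusted p under 0.05, 234 higher and 417 lower in Cal-0.

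Among the lower genes, AT1G76960 was at 2.27 ± 1.07 in Cal-0 and 395 ± 128 in Col-4 (log2 difference -4.44, standard error 0.21, limma adjusted p = 4.55e-07). Its Cal-0 signal was so low that the difference moved with the pseudocount, from -6.92 with 1 to -3.04 with 50, where AT1G23130 exceeded it at -3.53. AT1G23130, of the Bet v 1 allergen family, had a signal of 124 ± 25.6 against 1980.5 ± 442 (log2 difference -3.82, limma adjusted p = 5.35e-07). The thaumatin-like gene AT1G20030 and the defensin-like gene AT2G43535 differed by -2.61 and -2.16, and AT1G67865 by -3.28. ZW9, which encodes a protein with a TRAF-like domain, stood at 52.0 ± 6.66 in Cal-0 and 324 ± 11.8 in Col-4. The remaining genes in this set were AT2G32160 (log2 difference -2.59), AT5G63680 (log2 difference -2.53, and -3.83 and -1.62 with pseudocounts of 1 and 50), AT2G21860 (log2 difference -2.31) and AT3G22970 (log2 difference -2.22).

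Among the higher genes, AT3G48640 was at 161 ± 15.1 in Cal-0 and 6.12 ± 5.08 in Col-4 (log2 difference 3.02, limma adjusted p = 2.00e-06), the difference being 4.84 with a pseudocount of 1 and 1.91 with 50. AT2G29170, related to short-chain dehydrogenases, was at 311 ± 109 against 23.4 ± 7.07. The neighbouring extensin-like genes AT1G26250 and AT1G26240, whose products are structural cell wall proteins, were higher by 1.89 and 1.58 on the log2 scale. AT5G55450, of the lipid transfer protein family, was at 824 ± 154 in Cal-0 and 268 ± 52.3 in Col-4. AT3G29970 and AT5G10040, both known for induction under low oxygen, were higher by 2.00 and 1.81. AT5G15360, AT1G13470 and AT4G29200 completed the set with log2 differences of 2.59, 2.42 and 2.13, that of AT1G13470 running from 3.71 with a pseudocount of 1 to 1.57 with 50. In all 24 of these genes the 4 Cal-0 values lay on a single side of the 4 Col-4 values, as the rule for naming them required. Over all tested probe sets, 10.32% had groups without overlap, where chance gives 2.86% for 4 against 4.

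**Figure D1:**
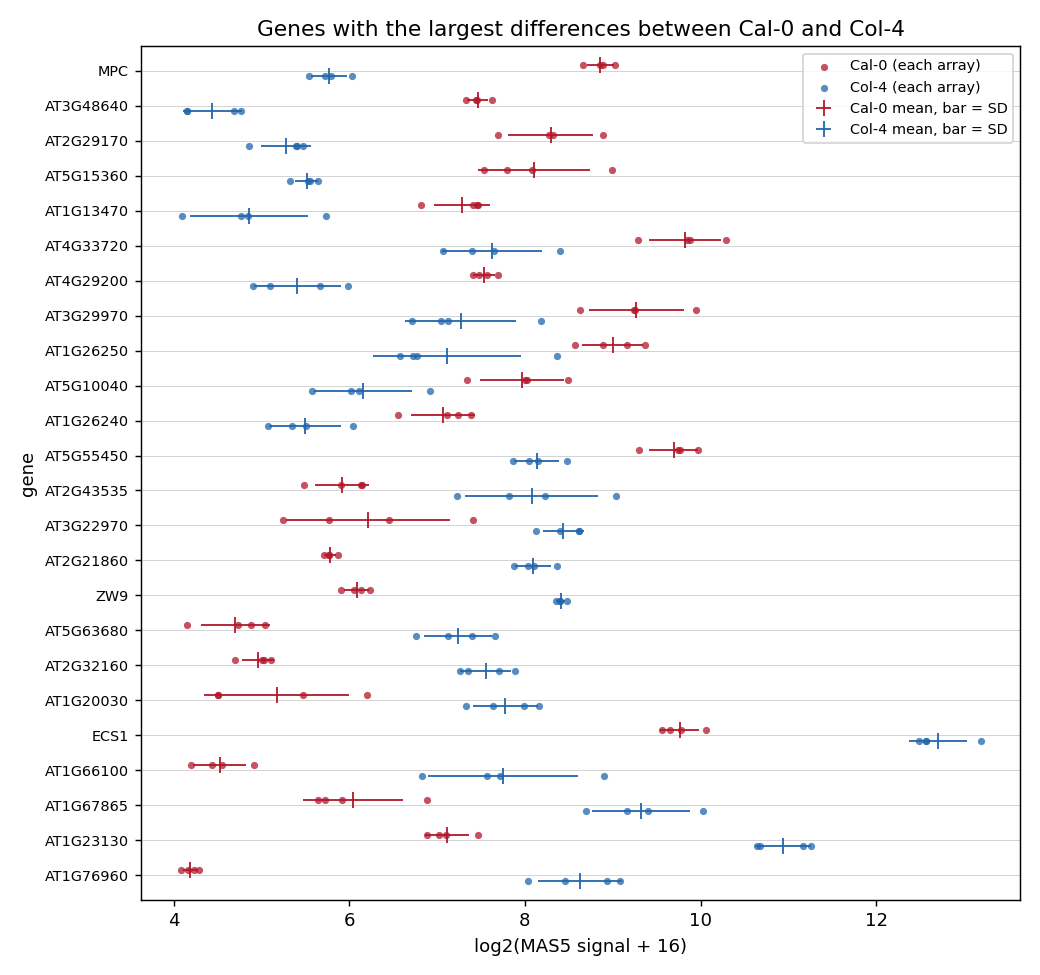
Signals of the 24 genes with the largest called differences, on a log2(MAS5 signal + 16) axis, with each array as a point, the mean as a tick and the SD as a bar (n = 4 arrays per accession). The points of Cal-0 and Col-4 do not overlap for any of them, and ECS1 has the highest Col-4 mean, 6788 signal units.

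On the log2(signal + 16) scale, 295 of the calls had at least a 2-fold difference, 102 higher and 193 lower in Cal-0. A difference of at least 4-fold was seen in 51, 16 higher and 35 lower. That count depended on the pseudocount, being 97 with 1 and 19 with 50. Arrays with the same replicate number varied together, but for replicates 1 and 2 arrays with unlike numbers did so as well. With the replicate number as a block 1299 probe sets passed, 548 higher and 751 lower. Arrays 1 to 4 of the titles also differed from arrays 5 to 8, each set holding 2 arrays of each accession. With that division as a block 1095 probe sets passed, and the accession difference within arrays 1 to 4 and within arrays 5 to 8, in a fit that shares its spread over all 8 arrays, gave 379 and 319. The log2 ratio of 3′ to 5′ signal of the GAPDH and actin controls, a sign of RNA quality, moved with the accession in arrays 1 to 4, where Cal-0 was at 1.70 and 1.52 and Col-4 at 0.955 and 0.927. In arrays 5 to 8 the accessions overlapped (Cal-0 1.89 and 1.97, Col-4 1.66 and 2.39), and with the ratio as a covariate, an alternative chosen after seeing the data, 868 probe sets passed. The count was 412 without Cal-0 replicate 1 and 413 without Col-4 replicate 2.

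Iron is hard to take up from lime-rich soils, and iron-deficiency genes were among the lists fixed for this comparison. IMA1 (AT1G47400), a peptide gene induced by iron deficiency, was the member of the iron-deficiency list that rose, at 287 ± 87.3 in Cal-0 against 110.0 ± 38.4 in Col-4 (log2 difference 1.28, limma adjusted p = 0.0105). The other 3 tested members, PYE, F6H1 and S8H, did not pass, and 1 of the 4 passed when adjusted over the list alone. The 4 differences were all positive, with a median of 0.44. The list's camera test gave an adjusted p of 0.177, and 0.53 with an estimated correlation; with the replicate number as a block it passed, at an adjusted p of 0.025. CHX16, of the family of cation/proton exchangers, was higher in Cal-0 (43.2 ± 8.88 against 10.7 ± 11.5, log2 difference 1.22), though not past the threshold without Cal-0 replicate 1. No member of the list of calcium pumps, exchangers and vacuolar channel, of ferritins or of phosphate starvation genes was analysed here, because the gene table used here named no probe set for them. Of the calcium sensors, CML42 (log2 difference 0.48, limma adjusted p = 0.348) and CML38 did not pass, and neither did the proton pump subunit gene VHA-A3 (log2 difference 0.21) nor the citrate transporter gene MATE (log2 difference -0.17).

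Glucosinolate genes moved in both directions. UGT74B1, the glucosyltransferase of glucosinolate core synthesis, was at 77.4 ± 10.2 in Cal-0 and 218 ± 18.5 in Col-4, a log2 difference of -1.33 (limma adjusted p = 0.000173). UGT74C1, linked to the methionine-derived glucosinolates, was higher in Cal-0 by 0.53 (limma adjusted p = 0.0428). BCAT4, which starts the chain elongation of methionine, was at 1624 ± 308 against 1154 ± 216 without passing. All 3 tested members passed when adjusted over the list alone, 2 of them over all probe sets. The list's median was 0.49 and its mean -0.10, and its camera test gave an adjusted p of 0.915.

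Among defence lists, THI2.1, a jasmonate-inducible thionin gene, fell in Cal-0 (30.03 ± 8.53 against 127 ± 73.6, log2 difference -1.50, limma adjusted p = 0.0214). PDF1.2, the other member tested, did not pass, and 1 of the 2 passed when adjusted over the list alone. LOV1, a nucleotide-binding leucine-rich repeat (NLR) receptor gene, was higher in Cal-0 by 0.76 and was the member tested of the disease resistance list. SAG101, the only tested member of the salicylic acid list, stood at 0.33 without passing over all probe sets (limma adjusted p = 0.2826), and with a single member an adjustment over the list alone leaves its unadjusted p of 0.0387 as it was.

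A larger, separate list of NLR receptor genes, without LOV1, was added after the gene table had been read and before any test. It had 32 tested members, of which 6 fell, 1 rose and 25 did not pass. AT4G19500 was at 10.4 ± 6.99 in Cal-0 and 96.9 ± 12.5 in Col-4, a log2 difference of -2.12, and AT3G44630, AT4G19530 and AT1G63880 differed by -1.92, -1.68 and -1.66. With pseudocounts of 1 and 50 the difference of AT4G19500 was -3.29 and -1.28, and that of AT3G44630 -3.05 and -1.125. Weaker binding of Cal-0 transcripts to probes designed on Columbia sequence, or loss of such genes in Cal-0, could also lower these signals. Neither was tested for this list. The list had 16 positive and 16 negative differences, a median of -0.003 and a mean of -0.29, and its camera test gave a call toward lower values in Cal-0 (adjusted p = 0.0256). The call was lost with an estimated correlation (adjusted p = 0.771) and with the replicate number as a block (adjusted p = 0.0889).

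DFR, an enzyme gene of anthocyanin synthesis, was at 470 ± 194 in Cal-0 and 1021 ± 377 in Col-4 (log2 difference -1.10, limma adjusted p = 0.0694), and both it and UF3GT passed when adjusted over the list alone. GI, a clock gene that also promotes flowering, was at 568 ± 57.7 against 387 ± 56.6 (log2 difference 0.54, limma adjusted p = 0.06). It was the only member tested of both the flowering and the clock list, so adjusting over either list alone leaves its unadjusted p of 0.00286 as it was. None of the 4 tested drought, salt and cold genes passed, COR47 having the smallest p (log2 difference 0.32). Of the senescence list, WRKY6 differed by 0.61 (limma adjusted p = 0.0522). With the replicate number as a block DFR, GI and WRKY6 passed, at limma adjusted p of 0.000824, 0.0203 and 0.0406. Of the senescence genes, 2 of 3 passed when adjusted over the list alone. The pectin list had ATPMEPCRB at 0.62 and none of 3 past the threshold. LHCB4.1 for photosynthesis (log2 difference -0.20), PYK10 for roots (log2 difference 0.35) and ATHSP22.0 for heat shock (log2 difference 0.25) did not pass. Of the reference genes, PEX4 fell in Cal-0 (99.5 ± 13.9 against 201 ± 26.4, log2 difference -0.91, limma adjusted p = 0.00359), while TIP41L and SAND did not pass.

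None of the 6 fixed lists with at least 3 tested members passed the camera test, with 1 at an unadjusted p under 0.05, and none passed with an estimated correlation; fry called 1, the reference genes (adjusted p = 0.03).

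In the gene families added in the same way, some members passed. CYP71B6 (467 ± 86.1 against 223 ± 24.98) and CYP71B23 rose in Cal-0 by 1.01 and 1.05, while CYP71B26 and CYP71B5 fell by 1.22 and 0.68, and the other 7 tested cytochromes P450 did not pass. The tau-class glutathione transferase genes GSTU16, GSTU26 and GSTU18 fell by 0.83, 0.71 and 0.68. The other 4 did not pass and had positive differences, GSTU22, GSTU27, GSTU20 and GSTU25 being at 0.80, 0.71, 0.45 and 0.34, and 6 of the 7 passed when adjusted over the list alone. The family's median was 0.34 and its mean 0.01, while its camera test pointed down (adjusted p = 0.811). The beta-glucosidase genes BGLU40 and BGLU47 fell by 0.98 and 0.87, with 6 others not past the threshold. That family, with a median of 0.10 and a mean of -0.16, passed with fry (adjusted p = 0.00519) but not with camera (adjusted p = 0.523, and adjusted p = 0.771 with an estimated correlation). ATG8F and ATG8C, which encode ubiquitin-like proteins of autophagosomes, fell by 0.66 and 0.52, and 6 further autophagy genes did not pass. RALFL34 and RALFL31, genes of secreted signalling peptides, fell by 0.72 and 0.74. The carboxypeptidase-like gene scpl42 stood at 17.6 ± 7.79 in Cal-0 and 121 ± 19.99 in Col-4, and XTH33 of the xyloglucan-modifying enzymes rose by 1.08. The plastid gene ndhD fell by 0.87, the only called member among 62 tested plastid genes in the 3 plastid lists. Apart from the NLR list, none of the 19 added lists tested passed the camera test, and none of the 19 did with an estimated correlation. No called named gene changed direction in any alternative, but 13 of the 51 called named genes lost their call in at least 1 alternative, namely CHX16, XTH33, LOV1, UGT74C1, ATG8C, ATG8F, GSTU18, CYP71B5, RALFL34, RALFL31, ndhD, CYP71B26 and THI2.1. A pseudocount of 1 or 50 also moved the differences of AT1G66100, CHX16, XTH33, LOV1, GSTU26, CYP71B5, RALFL31 and scpl42 by over 1.5 times, and among uncalled named genes those of WRKY6, SAG101, ATPMEPCRB, ATHSP22.0 and MATE; leaving out single arrays did so for the uncalled LHCB4.1, PYK10, VHA-A3, MATE and ATHSP22.0.

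**Figure D2:**
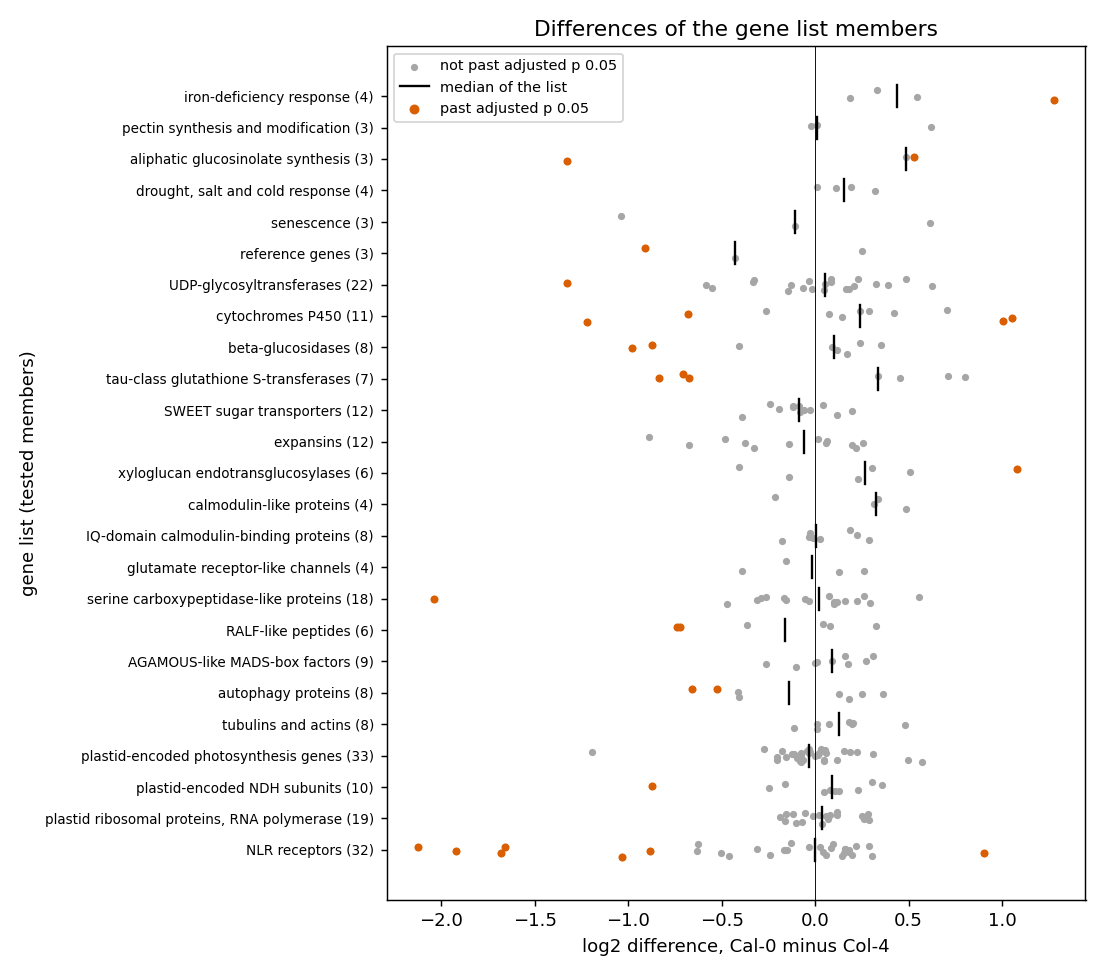
Log2 differences, Cal-0 minus Col-4, of the tested members of each gene list with at least 3 of them; each point is a gene, orange points passed the limma threshold, black ticks are list medians, and the number of tested members follows each name. The NLR list reaches down to -2.12 for AT4G19500 although its median is -0.003.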

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

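The test of scaling in the 4-fold calls and Fisher's test beside it were chosen only after the result was seen. Among 126 groups of 4 arrays behind the named genes, 8 held an array whose gap to the nearest other as a share of the group's range exceeded Dixon's 95% critical value on the log2(signal + 16) scale; chance gives about 1 group in 20. In Col-4 replicate 4, AT1G26250 was at 313 against 79.4 to 93.3 in the other Col-4 arrays, ECS1 at 9319 against 5713 to 6075, and AT4G19500 at 78.3 against 101 to 105. In Col-4 replicate 3, AT2G29170 was at 12.9 against 25.9 to 28.4, and CHX16 at 27.9 against 4.1 to 5.8. In Cal-0 replicate 2, AT1G13470 was at 96.5 against 154 to 160.0, and AT4G19530 at 51.8 against 44.0 to 44.5. In Cal-0 replicate 3, BGLU47 was at 36.7 against 56.3 to 60.4.

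The number of called probe sets was compared with that of other groupings of the arrays. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many as 651, the real split itself. The highest other count, 358, came from the split between arrays 1 to 4 and arrays 5 to 8, a structure of the samples, and 33 splits gave 0. The fit behind the 358 left the accession difference in its spread. These sets of arrays differed at 1032 probe sets in a fit with a mean for each accession in each set. Another fit, with the sets as a block, gave 1095 between the accessions, so these 2 counts are not from like fits. The 358 and 651 therefore do not rank the strength of these differences. If the replicate numbers pair the samples, the fitting comparison leaves out the 27 splits that keep at least 1 replicate pair together. Among the 8 that part all 4 pairs the highest other count was 0, but those are too few for a share under 0.05. Of the 379 probe sets called within arrays 1 to 4, 96.83% had the same sign in arrays 5 to 8, against 64.66% over all tested probe sets. In both sets of arrays the Cal-0 arrays carry the lower numbers, so an effect of array order within a set and the accession cannot be told apart.

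Calls of at least 4-fold leaned toward lower values in Cal-0, at 68.6% (exact 95% interval 54.1 to 80.9). After quantile normalization the share was 70.6%. The arrays were already at a common level, with a median log2 difference of 0.028 over all tested probe sets. Quantile normalization could therefore hardly have reversed such large differences, and its result decides little about array scaling. Weaker binding of Cal-0 transcripts to probes designed on Columbia sequence may contribute and stays open. The rule fixed beforehand pointed to it, since the 68.6% exceeded the share among calls under 2-fold, 62.9%. Fisher's exact test between the shares, added after the result was seen, gave p = 0.534, so the question was left undecided. True loss or lower expression of genes in Cal-0 stays open as well and was not tested. Weaker probe binding was also not tested for single genes with smaller decreases, such as UGT74B1 and PEX4.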

How the results depend on the processing

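The alternatives for the NLR list and the 3′ to 5′ covariate were chosen after seeing the data; all others were fixed beforehand. Of 51 called named genes, 38 kept direction and call in every alternative that gave them a value, and no named gene reversed; with a mean signal of at least 100, 31 of the 51 had a value. The probe set count of 651 became 1299 with the replicate block and 1095 with the block of arrays 1 to 4 against 5 to 8, each containing all 651, and 406 with a mean signal of at least 100, where 6614 were tested. Leaving out each array gave 412 to 672 (412 without Cal-0 replicate 1, 413 without Col-4 replicate 2). The count of fixed lists, 0, became 1 with no filter (jasmonate, lower), 1 with the replicate block (iron deficiency, higher) and 1 with fry; the cause was not tested. It was 0 without each array. The NLR list's adjusted p of 0.0256 ranged from 0.00368 to 0.771 over 17 alternatives and stayed past the threshold in 8. Among those 8, the mean of all probe sets of a gene left the camera adjusted p at 0.0256 and so was no separate check. The list's adjusted p was 0.668 with no filter, 0.0889 with the replicate block, 0.0664 with the block of arrays, 0.771 with an estimated correlation and 0.0747 with fry. Leaving out each array gave 0.00368 to 0.139, with the call lost without Col-4 replicate 1 (0.0628), Cal-0 replicate 3 (0.139), Cal-0 replicate 4 (0.0811) and Col-4 replicate 4 (0.0522). The replicate block ended no call of a named gene and brought 3 of the 12 uncalled ones, DFR, GI and WRKY6, past the threshold. No detection calls were used, so how far low signals stand above background was not measured.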

Other observations

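The low-oxygen tests, that of RNA quality on the same list included, the neighbouring-gene test and the use of the spread between like arrays to judge the RNA quality gap were chosen only after the result was seen. Several genes induced by low oxygen were higher in Cal-0. AT4G27450 was at 1148 in Cal-0 against 448 in Col-4 and AT1G19530 at 167 against 74.4, beside AT3G29970 and AT5G10040. These 4 prompted a list of 45 low-oxygen response genes, of which 25 were tested. Leaving the 4 out, 18 of 21 members had positive differences and 1 passed the threshold. Their median log2 difference was 0.458, where 10000 random gene lists matched on mean signal reached at most 0.25. A candidate explanation is a stronger low-oxygen response in the Cal-0 plants. With the 3′ to 5′ ratio as a covariate the median was 0.405, where random lists reached at most 0.3. That argues against RNA quality as the whole source only so far as the ratio of the GAPDH and actin controls measures it. Array by array the ratio and the list moved together only in part. On the log2(signal + 16) scale, Col-4 replicates 1, 2, 3 and 4 had list medians of 6.44, 6.80, 6.46 and 7.32 at ratios of 0.955, 0.927, 1.66 and 2.39, and Cal-0 replicates 1, 2, 3 and 4 had 7.60, 7.33, 6.94 and 7.52 at ratios of 1.70, 1.52, 1.89 and 1.97. A part played by RNA quality stays open. The median difference was 0.645 within arrays 1 to 4 and 0.369 within arrays 5 to 8. Col-4 replicate 4 lay inside the Cal-0 range. Members of a shared response are not independent, and watering, root mass and handling of the plants before harvest were not tested.

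Arrays 5 to 8 differed from arrays 1 to 4 at 1032 probe sets, 531 higher and 501 lower, in a limma fit with both accessions in each set of arrays. Within Cal-0 alone 0 probe sets passed, with 2202 at an unadjusted p under 0.05. Within Col-4 alone 64 passed, 38 higher and 26 lower, with 2916 at an unadjusted p under 0.05. Each of these compared 2 arrays with 2, in a fit that shares its spread over all 8 arrays. The plastid gene rpl36 averaged 145 in arrays 1 to 4 and 951 in arrays 5 to 8, and rpoA 577 and 1399. In the other direction TUB7 averaged 432 and 185, EXPA8 212 and 88.4, and the extensin gene HRGP1 546 and 236. Of the plastid ribosomal protein and RNA polymerase genes 6 were higher and 2 lower (camera adjusted p = 0.000981, and 0.711 with an estimated correlation). Of 22 UDP-glycosyltransferase genes 5 were higher and none lower (camera adjusted p = 0.000464, and 0.424 with an estimated correlation). Camera also called the drought, salt and cold list (adjusted p = 0.00362) and the plastid-encoded photosynthesis genes (adjusted p = 0.0147) toward higher values in arrays 5 to 8, and the SWEET transporters (adjusted p = 0.0224) toward lower ones. With an estimated correlation their adjusted p were 0.591, 0.723 and 0.591. Of these lists 1 of 4 genes, 1 of 33 and none of 12 were higher, and none, 1 and 1 lower. No probe set passed a limma test for a different accession effect between the sets of arrays, with 607 at an unadjusted p under 0.05.

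After quantile normalization 868 of the 1032 probe sets (84.1%) still differed between these sets of arrays, among 1015 in all. The rule fixed beforehand counted this against scaling as the source. The arrays were already at a common level before that step, so its result decides little about array scaling. RNA quality may contribute and stays open. The log2 ratio of 3′ to 5′ signal, averaged over the GAPDH and actin controls, was 0.927 to 1.70 in arrays 1 to 4 and 1.66 to 2.39 in arrays 5 to 8. The rule fixed beforehand counted overlapping ranges against RNA quality, and the ranges overlapped, with a gap of -0.041. That overlap is within the spread between like arrays (SD 0.267), a standard chosen later, so it was not taken to decide the question. In arrays 1 to 4 the ratio also separated the accessions, Cal-0 having the higher values. Within each accession the later-numbered arrays had the higher ratios. The mean went from 1.611 to 1.925 in Cal-0 and from 0.941 to 2.024 in Col-4. No biological explanation was tested, since the labels give no other condition.

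The positions of called genes were compared in the gene order of TAIR10.1. Of 351 called genes, 9.69% had another called gene within 2 genes on either side, against a median of 4.56% in 10000 random draws. The bound set for the test was the highest draw, 11.11%, and was not reached, though 18 draws came as high. In 15 of the 17 pairs both genes differed in the same direction, where chance gives 55.6% of pairs, such as AT1G67860 and AT1G67865 (-1.60 and -3.28) and AT4G16870 and AT4G16880 (-1.23 and -1.91). Local sequence differences between the accessions, or probes shared by duplicated neighbours, could produce such pairs and were not told apart.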
